A study of Mus musculus with 30 samples.

How the data were processed

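A20 cells, a B-cell lymphoma line from the BALB/c mouse, were injected intravenously (500000 cells) into wild type or Sparc-null recipients, and were recovered by flow sorting from bone marrow, spleen and liver 5 weeks later, per the labels' protocols. Sparc encodes a matricellular protein, and the genotype is that of the recipient, whereas the labels give no change to the injected cells. Each of the 6 combinations of recipient genotype and organ held 5 libraries, 30 in all. The series design states 5 mice per genotype, while the replicate numbers of the wild type spleen libraries run up to 11, so the labels do not say which libraries came from the same animal. The p-values measure the spread between these libraries.

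Total RNA was depleted of ribosomal RNA and made into libraries with a kit that marks the strand, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR and HTSeq, without a version of the last pair and without the strand setting of the counting. The deposited values are raw counts of reads per gene identifier, not normalized. Each library lists 40303 identifiers of the BALB/cJ strain annotation and 5 summary lines. The summary lines for unaligned, low-quality and multiply mapped reads held 0 reads in every library. Of the tallied reads, between 96.6% and 98.7% were tallied as in no gene, between 0.0139% and 0.0285% were ambiguous, and between 1.28% and 3.33% were counted for a gene (median 2.98%). The summary lines were left out of library sizes and tests. Reads of a gene and of an antisense or overlapping gene cannot be told apart where the strand setting is not known, and counting on the opposite strand would leave a small assigned share. No gene identity below is therefore certain to be that of the sense transcript.

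The files do not pair identifiers with gene names, and 0 of the 40303 identifiers matched the gene tables used here. Lists of pathway genes and of markers of other cell types had been fixed before the data were examined, together with the tests and most alternatives. Neither these lists nor the level of Sparc was analysed here, so the genotype labels were not checked against the deleted gene. Identifiers are printed as deposited, at most 2 higher and 2 lower per comparison. The rule took identifiers with adjusted p under 0.05, a mean of at least 10 CPM in both groups and no overlap between the 5 libraries of each group, ranked by log2 fold change. It was set for the organ comparisons in wild type recipients and for the genotype comparisons, and the values of the same identifiers are given in Sparc-null recipients.

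Counts were analysed in R 4.3.3 with edgeR 4.0.16. Identifiers were kept by filterByExpr (minimum count 10), which left 10882 of the 26926 identifiers with a read and 99.2% of gene-assigned reads. Library sizes were scaled by TMM, all 30 libraries were fitted together by group without a replicate block, and groups were compared with the robust quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg within a comparison. CPM values were computed here from the deposited counts with the TMM-scaled library sizes. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Library measures were compared by two-sided exact permutation tests over all 252 splits of 5 against 5 libraries, adjusted over 36 tests. A gene with 0 reads in a library could hold up to 3 counts, or 0.9 CPM in the deepest and 6.79 CPM in the shallowest library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group were copies, with 0 identical files among 60 pairs and a lowest chi-square per degree of freedom of 5.61.

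The test was checked on simulated counts with 200 changed identifiers, drawn with each identifier's mean over all libraries and the real library sizes. The changed identifiers were taken only from those with an expected count of at least 10 at the median library size. Each comparison had a single draw per setting of the spread, with 66 or 67 changed identifiers per fold. All simulated wild type bone marrow libraries had the spread estimated with replicate 1 included, although part of that spread lay in that library. False calls and recovery where wild type bone marrow was compared may therefore differ in the real counts. With the same spread in all groups, the fit of all libraries made between 1 and 6 false calls per comparison. With each group's own spread, it made 35 false calls for bone marrow against spleen and 71 for liver against bone marrow in wild type recipients, and 179 for Sparc-null against wild type bone marrow. In the other 6 comparisons it made at most 4. With only the 2 compared groups in the fit, the false calls were between 0 and 7 in every comparison. For liver against spleen in wild type recipients, simulated 2-fold changes were recovered at 8.96% by the fit of all libraries and at 38.8% by the fit of the 2 groups, and 4-fold changes at 63.6% and 86.4%. The fit of the 2 groups recovered far fewer changes where wild type bone marrow was compared. Recovery of 4-fold changes fell there from 57.6% to 15.2% for bone marrow against spleen, from 68.2% to 0% for liver against bone marrow and from 69.7% to 1.52% for Sparc-null against wild type bone marrow. In the real counts, the fit of the 2 groups called 72 identifiers for liver against bone marrow in wild type recipients. The fit of all libraries called 7 for Sparc-null against wild type bone marrow, below the 179 false calls simulated there. Because neither fit was best in all simulated comparisons, the count from the fit of the compared groups is given beside each count from all libraries.

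The alternatives were DESeq2 1.42.0, the DESeq2 size factors in edgeR, no filter, only the compared groups in the fit, voom with sample quality weights (limma 3.58.1), the replicate number as a block, and each library left out in turn. Scaling by the library total, thinning to equal depth without wild type bone marrow replicate 1, the fit of the compared groups without that library, leaving out libraries outside the compared groups, and leaving out libraries for the library measures were chosen after seeing the data. Agreement between comparisons was measured by Pearson's r across identifiers, which are not independent replicates. The plots were drawn with matplotlib 3.10.9.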

Results

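Gene expression was profiled in A20 lymphoma cells recovered from 3 organs of wild type and Sparc-null recipients, with 5 libraries for each organ and genotype. The number of reads assigned to genes ranged from 169979 in wild type bone marrow replicate 1 to 3949038 in wild type spleen replicate 3. The next shallowest library, wild type bone marrow replicate 2, held 1003776. Wild type bone marrow replicate 1 also had the fewest identifiers with a read, 5089 against a median of 16050 over the 30 libraries. By group, the libraries held 169979 to 2117972 gene-assigned reads in wild type bone marrow, 2183684 to 3949038 in wild type spleen and 1986285 to 2747676 in wild type liver. The ranges in Sparc-null recipients were 1343073 to 2215360 in bone marrow, 2159676 to 2462488 in spleen and 2360873 to 2775336 in liver.

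A single identifier, MGP_BALBcJ_G0028184, held 25.1% of all gene-assigned reads, and its mean share was lowest in bone marrow. It was singled out after its values were seen. In wild type recipients its share was 15.0% ± 10.5 in bone marrow, 28.9% ± 1.48 in spleen and 25.4% ± 4.90 in liver (SD, n = 5 each). In Sparc-null recipients the shares were 15.8% ± 5.80, 25.3% ± 1.08 and 29.4% ± 2.38 (SD, n = 5 each). Bone marrow differed from spleen in both genotypes by an exact permutation test (p = 0.00794 each, adjusted p = 0.0238, the smallest p that 5 against 5 libraries can give). In wild type recipients the exact p was 0.0556 without wild type spleen replicate 3. Liver had a higher share than bone marrow in Sparc-null recipients (exact permutation p = 0.00794, adjusted p = 0.0238), while in wild type recipients the difference of 10.5 points did not pass (exact permutation p = 0.0873, adjusted p = 0.131). In Sparc-null recipients the share was also 4.10 points higher in liver than in spleen (exact permutation p = 0.0238, adjusted p = 0.0476). In spleen the share was 3.66 points lower in Sparc-null than in wild type recipients, with all 5 libraries of each genotype apart (exact permutation p = 0.00794, adjusted p = 0.0238). The percentage of tallied reads assigned to genes was also lower in Sparc-null than in wild type spleen, at 2.99% ± 0.0819 against 3.25% ± 0.0585 (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0238). In the TMM-scaled fit of counts, however, no organ difference of this identifier passed (edgeR adjusted p = 0.0948 for bone marrow against spleen in wild type and 0.286 in Sparc-null recipients). Its genotype difference in spleen did not pass there either, since 0 identifiers were called in that comparison. The percentage of tallied reads assigned to genes was also lower in bone marrow than in spleen, at 2.33% ± 0.679 against 3.25% ± 0.0585 in wild type and 2.53% ± 0.304 against 2.99% ± 0.0819 in Sparc-null recipients (SD, n = 5 each, exact permutation p = 0.00794 and 0.0159, adjusted p = 0.0238 and 0.0358). Between liver and spleen this percentage differed by -0.278 points in wild type and by 0.123 points in Sparc-null recipients (exact permutation p = 0.00794 and 0.0238, adjusted p = 0.0238 and 0.0476), and in Sparc-null recipients it was 0.581 points higher in liver than in bone marrow (exact permutation p = 0.00794, adjusted p = 0.0238).

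**Figure D1:**
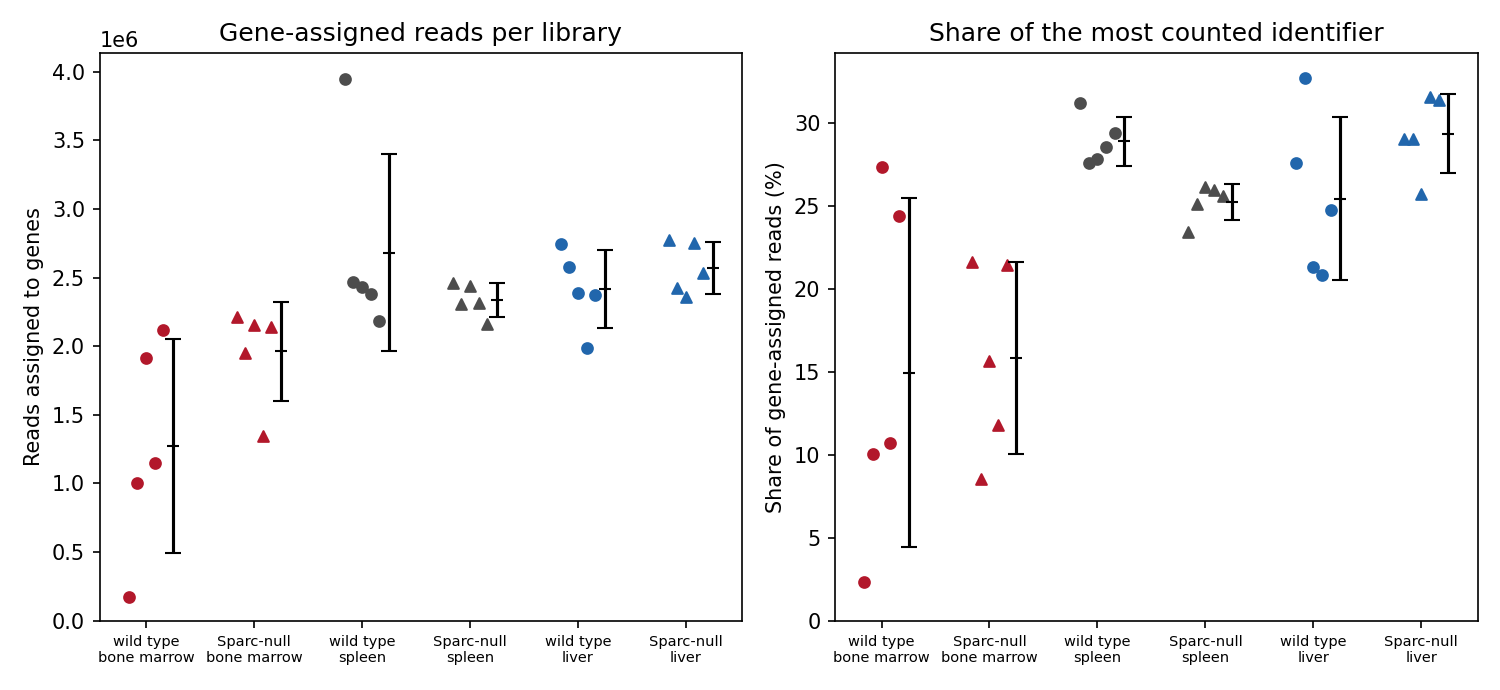
Reads assigned to genes (left) and the percentage of them on the most counted identifier (right), one point per library, with circles for wild type and triangles for Sparc-null recipients and bars for the mean and SD of 5 libraries. Bone marrow libraries spread from 2.30% to 27.3% on the right, while spleen libraries lie between 23.5% and 31.2%.

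The bone marrow libraries varied most among themselves. The biological coefficient of variation within a group was 84.3% in wild type bone marrow (65.7% without replicate 1) and 54.8% in Sparc-null bone marrow. It was 30.2% and 32.8% in wild type and Sparc-null spleen and 32.1% and 41.1% in wild type and Sparc-null liver. With all libraries, the first principal component of log2 CPM (31.6% of variance) set wild type bone marrow replicate 1 apart. Without it, the first component (23.8%) separated bone marrow from spleen and liver, except for wild type bone marrow replicate 3, which lay within the range of the spleen and liver libraries on that component.

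**Figure D2:**
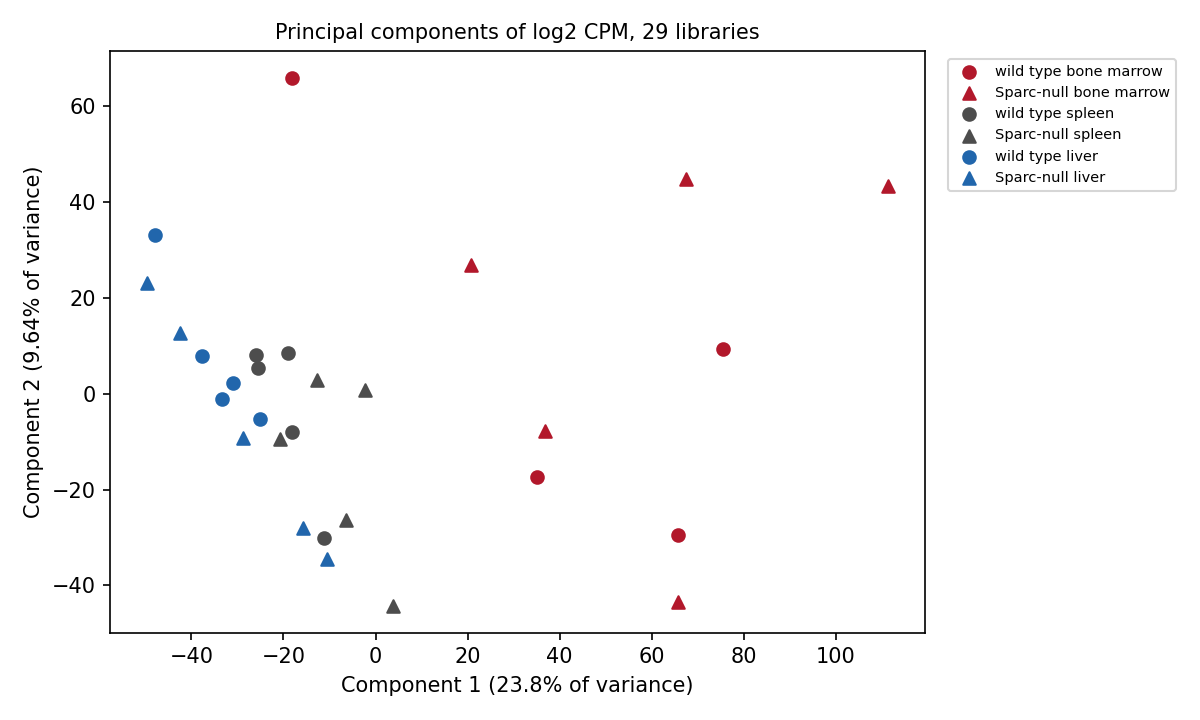
First 2 principal components of log2 CPM of the 29 libraries other than wild type bone marrow replicate 1, one point per library, coloured by organ. Component 1 carries 23.8% and component 2 carries 9.64% of the variance, and all bone marrow libraries but 1 lie to the right.

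The first comparison asked how lymphoma cells in bone marrow differed from those in spleen of the same recipient genotype. In wild type recipients 242 identifiers were higher and 207 lower in bone marrow, and in Sparc-null recipients 526 were higher and 123 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). MGP_BALBcJ_G0009206 was higher in wild type bone marrow by a log2 fold change of 4.62 ± 0.97 (SE), at 4702 ± 5850 against 190.8 ± 81.9 CPM (SD, n = 5 each, edgeR adjusted p = 0.00957), and MGP_BALBcJ_G0007650 by 4.15 ± 0.76, at 473.8 ± 750 against 26.1 ± 3.90 CPM (edgeR adjusted p = 0.00426). Both means rested in large part on replicate 1, without which the log2 fold changes were 3.51 and 2.44. MGP_BALBcJ_G0035991 was lower in bone marrow, with a log2 fold change of -1.79 ± 0.41 (14.2 ± 10.3 against 53.2 ± 10.1 CPM, edgeR adjusted p = 0.00979), as was MGP_BALBcJ_G0019924, with -1.64 ± 0.36 (322.3 ± 202 against 1013 ± 170 CPM, edgeR adjusted p = 0.00829).

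In Sparc-null recipients MGP_BALBcJ_G0019924 was also lower in bone marrow, with a log2 fold change of -1.44 ± 0.35 (edgeR adjusted p = 0.00975). The other 3 identifiers had log2 fold changes in the same direction without passing the test, at 1.28 for MGP_BALBcJ_G0009206, 1.25 for MGP_BALBcJ_G0007650 and -1.08 for MGP_BALBcJ_G0035991 (edgeR adjusted p = 0.446, 0.337 and 0.096). The 5 libraries of each organ did not overlap for 4.97% of the 10882 tested identifiers in wild type and 7.65% in Sparc-null recipients, where chance gives 0.794%. The Sparc-null count was 683 with only the 2 groups in the fit. The wild type count was 38 in that fit (36 higher and 2 lower), where MGP_BALBcJ_G0007650, MGP_BALBcJ_G0035991 and MGP_BALBcJ_G0019924 no longer passed (edgeR adjusted p = 0.0844, 0.165 and 0.086), and it was 505 in the fit of the 29 libraries other than wild type bone marrow replicate 1. In simulated data with the spread of each group, the fit of all libraries made 35 false calls in the wild type comparison, while the fit of the 2 groups made 1 and recovered 15.2% of 4-fold changes against 57.6% with all libraries.

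Lymphoma cells in liver were compared with those in spleen. In wild type recipients 4 identifiers were higher and 2 lower in liver, and in Sparc-null recipients 18 were higher and 8 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, all libraries). MGP_BALBcJ_G0026991 was higher in wild type liver by a log2 fold change of 2.09 ± 0.42 (SE), at 57.0 ± 27.9 against 13.3 ± 4.64 CPM (SD, n = 5 each, edgeR adjusted p = 0.0278), and MGP_BALBcJ_G0004441 by 1.91 ± 0.40, at 48.3 ± 19.5 against 12.8 ± 3.78 CPM (edgeR adjusted p = 0.043). MGP_BALBcJ_G0004281 was lower in liver, with -2.06 ± 0.35 (16.1 ± 9.65 against 66.9 ± 4.54 CPM, edgeR adjusted p = 0.00401), and so was MGP_BALBcJ_G0020850, with -1.84 ± 0.32 (31.5 ± 12.3 against 113.0 ± 34.8 CPM, edgeR adjusted p = 0.00401). In Sparc-null recipients MGP_BALBcJ_G0004441 was likewise higher (log2 fold change 2.21 ± 0.40, edgeR adjusted p = 0.00854) and MGP_BALBcJ_G0004281 lower (-1.84 ± 0.35, edgeR adjusted p = 0.0113), while MGP_BALBcJ_G0026991 and MGP_BALBcJ_G0020850 had log2 fold changes of 0.68 and -0.84 (edgeR adjusted p = 0.762 and 0.403). The wild type calls of MGP_BALBcJ_G0026991 and MGP_BALBcJ_G0004441 each ended when single liver or spleen libraries were left out, with edgeR adjusted p of up to 0.144 and 0.191.

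These counts depended on which libraries shared the estimate of the spread. With only liver and spleen libraries in the edgeR fit, 437 identifiers were higher and 495 lower in liver of wild type recipients, and 141 were higher and 102 lower in liver of Sparc-null recipients. The median size of the log2 fold change of these calls was 0.79 and 1.09. Voom with sample quality weights called 1097 (527 higher and 570 lower) and 233 identifiers and DESeq2 called 183 and 121, and without wild type bone marrow replicate 1 the edgeR fit of the other 29 libraries called 224 (77 higher and 147 lower) and 74 (33 higher and 41 lower). At equal depth 47 were higher and 103 lower in liver of wild type and 20 higher and 30 lower in liver of Sparc-null recipients. The 5 libraries of liver and of spleen did not overlap for 7.52% of the 10882 tested identifiers in wild type and 5.03% in Sparc-null recipients, where chance gives 0.794%.

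Liver was also compared with bone marrow. In wild type recipients 413 identifiers were higher and 373 lower in liver, and in Sparc-null recipients 431 were higher and 703 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). MGP_BALBcJ_G0033750 was higher in wild type liver by a log2 fold change of 2.82 ± 0.55 (SE), at 86.0 ± 45.9 against 10.9 ± 8.56 CPM (SD, n = 5 each, edgeR adjusted p = 0.00229), and MGP_BALBcJ_G0018453 by 2.58 ± 0.45, at 129.5 ± 60.5 against 20.1 ± 16.9 CPM (edgeR adjusted p = 0.000599). MGP_BALBcJ_G0004705 was lower in liver, with -4.42 ± 0.86 (10.9 ± 11.7 against 234.7 ± 215 CPM, edgeR adjusted p = 0.00334), and MGP_BALBcJ_G0033815 with -4.05 ± 0.64 (13.5 ± 8.06 against 223.5 ± 140 CPM, edgeR adjusted p = 0.000546). All 4 passed in the same direction in Sparc-null recipients, where MGP_BALBcJ_G0033750 had a log2 fold change of 2.89 ± 0.54, MGP_BALBcJ_G0018453 of 2.996 ± 0.46, MGP_BALBcJ_G0004705 of -7.04 ± 0.98 and MGP_BALBcJ_G0033815 of -7.39 ± 0.74 (edgeR adjusted p = 0.000395, 1.67e-05, 2.66e-05 and 2.48e-07).

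MGP_BALBcJ_G0004705 and MGP_BALBcJ_G0033815 were also higher in bone marrow than in spleen in both genotypes. Their log2 fold changes were 2.89 ± 0.79 and 3.85 ± 0.63 in wild type and 3.66 ± 0.81 and 4.54 ± 0.63 in Sparc-null recipients (SE, edgeR adjusted p = 0.041, 0.00173, 0.00606 and 5.27e-05). The 5 libraries of liver and of bone marrow did not overlap for 5.72% of the 10882 tested identifiers in wild type and 9.02% in Sparc-null recipients (0.794% by chance). The call of MGP_BALBcJ_G0033750 in wild type recipients ended with voom (adjusted p = 0.0747). With only the compared groups in the fit, 21 identifiers were higher and 51 lower in liver of wild type recipients, and 845 were called in Sparc-null recipients. Those lower in wild type liver also outnumbered those higher with voom (192 and 94), at equal depth (263 and 134) and with library totals (1424 and 292). So they did without wild type bone marrow replicate 1 (440 and 301) and without a filter on low counts (642 and 537). There, those higher outnumbered those lower with the DESeq2 size factors (544 and 392), DESeq2 (905 and 586) and the replicate block (250 and 169). For the wild type comparison, the fit of all libraries made 71 false calls in simulated data and recovered 68.2% of 4-fold changes, while the fit of the 2 groups made 0 and recovered 0%. The simulation does not describe the fit of the 2 groups well, since it called 21 higher and 51 lower in the real counts. Identifiers lower in liver outnumbered those higher in Sparc-null recipients with TMM, whereas with the DESeq2 size factors 640 were higher and 602 lower.

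**Figure D3:**
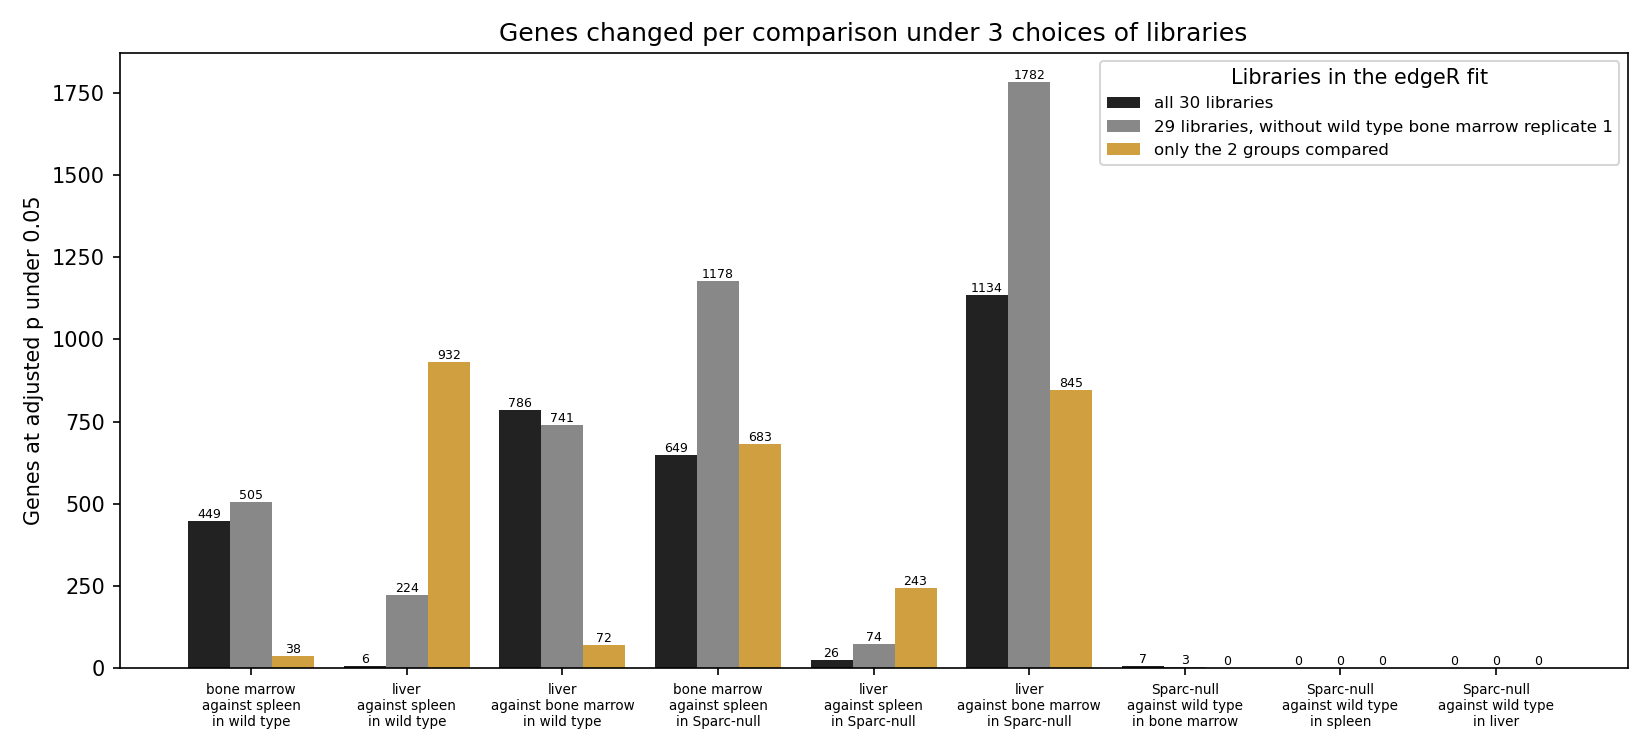
Number of identifiers at adjusted p under 0.05 (edgeR) in each comparison of 2 groups, with all 30 libraries in the fit (black), without wild type bone marrow replicate 1 (grey) and with only the compared groups (yellow). Liver against spleen in wild type recipients rose from 6 to 224 and 932, and bone marrow against spleen in wild type recipients went from 449 to 505 and 38.

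The organ differences were then set side by side between the recipient genotypes, which share no libraries. Of the identifiers called for bone marrow against spleen, 152 were higher and 39 lower in both genotypes and 0 went in opposite directions, where independent lists would share 11.7 and 2.34. For liver against bone marrow, 121 were higher and 244 lower in both and 0 were opposite (16.4 and 24.1 for independent lists). For liver against spleen, 3 were higher and 1 lower in both. In the fits of liver and spleen alone, 60 were higher and 73 lower in both genotypes and 0 were opposite (6.94 and 6.17 for independent lists). The fits of the compared groups alone gave smaller overlaps for bone marrow, with 26 higher and 1 lower in both genotypes against spleen (1.82 and 0.0489 for independent lists), and 12 higher and 40 lower in liver against bone marrow (0.798 and 2.76). Across the 10882 identifiers, Pearson's r between the log2 fold changes of the genotypes was 0.568 for bone marrow against spleen, 0.431 for liver against spleen and 0.654 for liver against bone marrow. Bone marrow effects also overlapped between genotypes when a different organ served as the reference: 176 identifiers were higher and 28 lower in wild type bone marrow than in wild type spleen and in Sparc-null bone marrow than in Sparc-null liver, with 0 opposite (15.6 and 8.2 for independent lists). For Sparc-null bone marrow against spleen and wild type bone marrow against liver, 169 were higher and 18 lower in both and 2 were opposite (18.0 and 4.67 for independent lists).

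**Figure D4:**
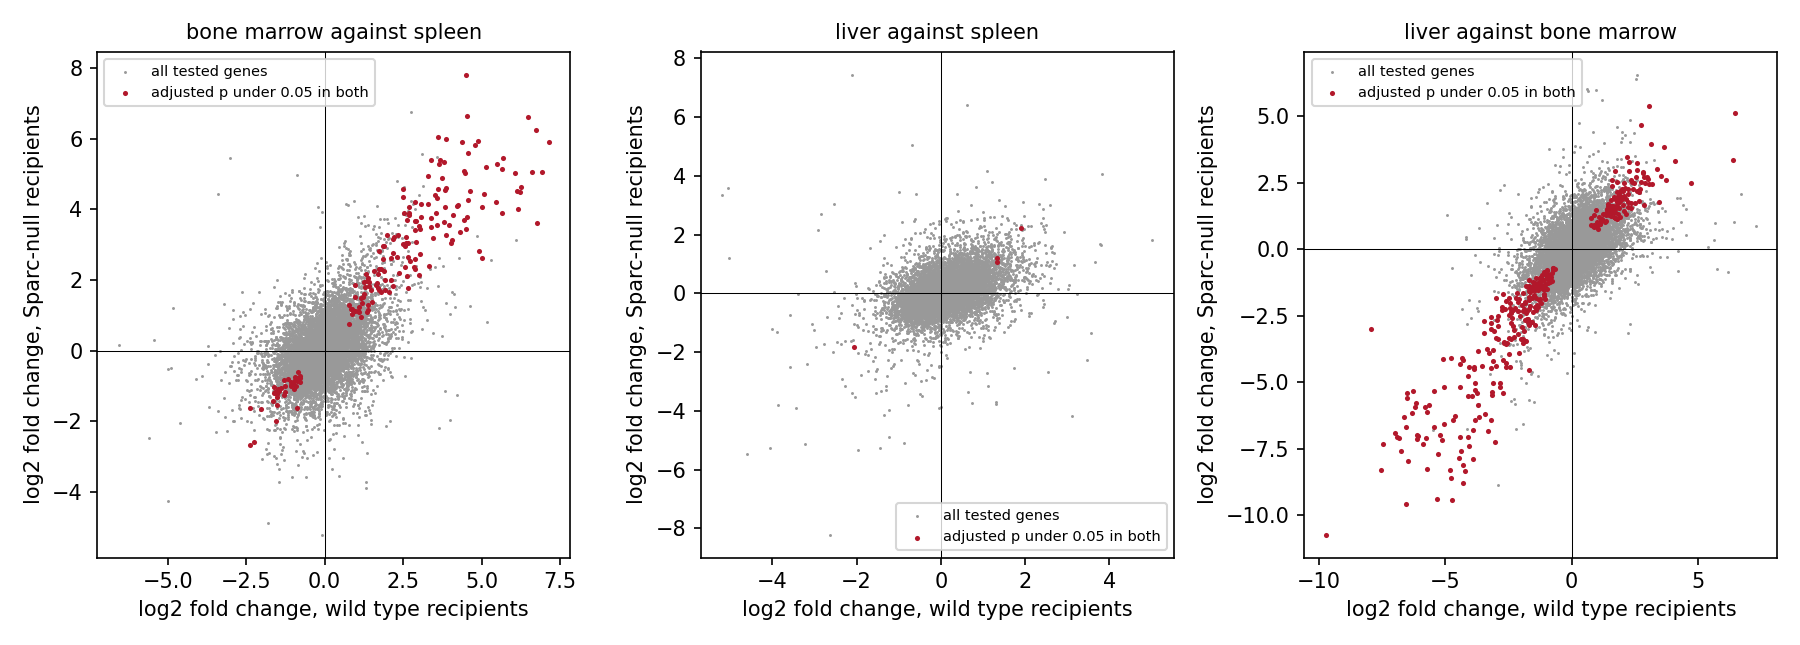
Log2 fold change of each tested identifier in wild type (x axis) and Sparc-null recipients (y axis) for the 3 organ comparisons, with identifiers at adjusted p under 0.05 in both genotypes in red. All red points lie in the quadrants of equal sign, and Pearson's r is 0.568, 0.431 and 0.654 from left to right.

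Lymphoma cells from Sparc-null recipients were compared with those from wild type recipients within each organ. In bone marrow 7 identifiers were higher and 0 lower in Sparc-null recipients (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). At unadjusted p under 0.05 lay 1375, where about 544 would be expected by chance. With only the compared groups in the edgeR fit there were 312, where 403 would be expected. Among the identifiers tested with all libraries, 0.974% had no overlap between the genotypes in bone marrow, close to the 0.794% that chance gives. MGP_BALBcJ_G0034392 alone met the rule for naming, with a log2 fold change of 1.27 ± 0.27 (SE), 213.7 ± 57.5 against 87.5 ± 30.6 CPM (SD, n = 5 each) and no overlap between the libraries of the genotypes (edgeR adjusted p = 0.049). This call ended in 27 of 39 alternatives, among them the fit of the compared groups (edgeR adjusted p = 0.859) and the fit without wild type bone marrow replicate 1 (edgeR adjusted p = 0.0814), and the adjusted p reached 0.997 with voom. Simulated data with the spread of each group gave 179 false calls for this comparison in the fit of all libraries, which recovered 69.7% of 4-fold changes, while the fit of the 2 groups made 0 false calls and recovered 1.52%. The real count of 7 lay far below 179, so these simulated rates may not hold for the real comparison. The count of 7 became 0 with the compared groups alone and 0 with voom, but 200 with DESeq2 (109 higher and 91 lower). Without a filter on low counts 134 were higher and 103 lower, and at equal depth 0 were higher and 1 lower. With single libraries left out, the count ranged from 0 without Sparc-null bone marrow replicate 3 to 171 without wild type bone marrow replicate 5.

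In spleen 0 identifiers differed between genotypes with edgeR, with 196 at unadjusted p under 0.05, and DESeq2 and voom also called 0. In liver 0 differed with edgeR, with 285 at unadjusted p under 0.05, DESeq2 called 1 and voom 0. About 544 unadjusted p-values under 0.05 would be expected by chance in these fits. With only the compared groups in the edgeR fit, 0 passed in either organ, with 637 at unadjusted p under 0.05 in spleen and 654 in liver, where 410 and 437 would be expected. In simulated data such fits recovered 89.4% of 4-fold and 37.3% of 2-fold changes in spleen and 81.8% and 26.9% in liver. Most simulated changes of 2-fold or less were thus not recovered at this depth and spread. The simulated changes lay in the better counted identifiers only, so recovery in the others is not shown. Without a filter on low counts, 26 identifiers were called in spleen and 46 in liver. Among the identifiers tested with all libraries, 1.42% in spleen and 1.05% in liver had no overlap between the genotypes, where chance gives 0.794%. Pearson's r between the genotype effects of 2 organs was 0.137 for bone marrow and spleen, 0.0377 for bone marrow and liver and 0.069 for spleen and liver.

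Whether the effect of recipient genotype differed between organs was tested directly. With edgeR, 0 identifiers passed for bone marrow against spleen, 0 for liver against spleen and 0 for liver against bone marrow. At unadjusted p under 0.05 lay 580, 183 and 729, where about 544 would be expected by chance in each. The fits of only the groups involved also called 0 in each. They had 326, 588 and 416 at unadjusted p under 0.05, where 487, 493 and 508 would be expected. DESeq2 called 0, 2 and 2, and voom called 0 in each. Without the filter on low counts, edgeR called 26, 29 and 73. With the filter, an identifier called for an organ difference in a single genotype was not shown to differ between genotypes by edgeR.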

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

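The tests on the reads in no gene and on equal depth were chosen after the results were seen. Sample values were compared within 50 groups of 5 libraries, of which 6 held a library far from the others, and chance gives about 5% of independent groups. The 50 groups are not independent, since a library can stand out in several measures. Some hold CPM of identifiers picked for large fold changes in the same libraries. The number found can therefore not be set against chance. Wild type spleen replicate 3 had 3949038 gene-assigned reads and 17463 identifiers with a read, above the other wild type spleen libraries (up to 2466035 and 15747). Sparc-null bone marrow replicate 4 had 13119 identifiers with a read, below the other 4 (15489 to 16327). In Sparc-null liver replicate 5, 3.02% of tallied reads were assigned to genes, against 3.11% to 3.14% in the other 4. MGP_BALBcJ_G0009206 reached 14900 CPM and MGP_BALBcJ_G0007650 reached 1807 CPM in wild type bone marrow replicate 1, against at most 3802 and 231.1 CPM in the other 4. The reads that no comparison used, those tallied as in no gene, had a median share of 97.0%.

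In all 30 libraries few of the tallied reads were counted for a gene. The lowest share tallied as in no gene was 96.64%, and this tally can hold reads within a gene on its other strand. Reads from ribosomal or unannotated RNA are a candidate explanation, although the protocols state that ribosomal RNA was depleted. Counting on the strand opposite to the library's is another, which may also leave a few percent, as in the median of 2.98% assigned. The counts hold neither coordinates nor the other strand's reads, so these explanations cannot be told apart. No biological explanation was tested.

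Wild type bone marrow replicate 1 stood apart from every other library. Its few reads alone were argued against, since when the other 29 libraries were thinned to its total, the lowest still had 8708 identifiers with a read, against its 5089. A label of another organ was argued against by its profile, which correlated better with the nearer bone marrow mean than with the nearest spleen or liver mean, by 0.0666 in r (at least 0.0631 with any marrow library left out of the mean). A score of the identifiers higher in Sparc-null bone marrow than spleen went the other way. It was 3.733 in this library, 4.444 to 5.502 in the other wild type bone marrow libraries and 3.772 to 4.036 in wild type spleen. The correlation alone therefore does not settle the label. A low number of distinct molecules in the library, or other properties of that animal or sort, may account for it and stay open, untested.

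More identifiers differed between bone marrow and spleen (649) than between liver and spleen (26) in Sparc-null recipients, in the fit of all libraries. The counts were 746 and 50 at equal depth and 693 and 33 without the most counted identifier. Neither library size nor that identifier therefore accounts for the gap in fits that hold all groups. These checks do not address the spread that the groups share in such fits. RNA from other cells in the bone marrow sort could raise marrow-higher identifiers as the most counted identifier's share falls, but r around the genotype means was -0.029 over the 10 bone marrow libraries (permutation p = 0.94, Spearman rho = -0.0909, p = 0.83). It was -0.627 without wild type bone marrow replicate 1 (permutation p = 0.078) and -0.492 without the 2 libraries farthest from the median share (permutation p = 0.21). By genotype, r was -0.572 in Sparc-null and 0.238 in wild type bone marrow (n = 5 each). The bound set beforehand against this explanation, an r over -0.3, was met by the value over the 10 libraries. The bound set beforehand for it was met by the value without wild type bone marrow replicate 1. The added demand that the first bound be met with each library left out was made after the value over the 10 libraries was seen, so this explanation stays open. The organ itself also stays open. With the compared groups alone, the counts were closer in Sparc-null recipients (683 and 243) and in the other order in wild type recipients (38 and 932). Voom, with all libraries in the fit, also gave closer counts in Sparc-null recipients (852 and 233). In simulated data, 2-fold changes between liver and spleen of Sparc-null recipients were recovered at 2.99% by the fit of all libraries. The fit of the 2 groups recovered 20.9%. The shared estimate of the spread is therefore a candidate for part of the gap.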

How the results depend on the processing

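Counts of changed identifiers depended strongly on the processing. Agreement of organ effects between genotypes kept its sign under 32 alternatives (10 CPM floor, DESeq2 size factors, left-out libraries). These could hardly reverse that sign. Scaling by library total, equal depth and leaving out libraries outside the compared groups were chosen after seeing the data. Counts follow in the order bone marrow against spleen, liver against spleen and liver against bone marrow, which were 449, 6 and 786 in wild type and 649, 26 and 1134 in Sparc-null recipients, and then Sparc-null against wild type bone marrow, which was 7. Only counts moved by over 1.5 times are listed.

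With the DESeq2 size factors, liver against spleen in wild type gave 36 and the genotype comparison in bone marrow 3. Without a filter the wild type counts were 774 and 120, liver against spleen in Sparc-null 159, and the genotype counts 237 in bone marrow, 26 in spleen and 46 in liver, with 26, 29 and 73 for the differences of genotype effects, in the organ order above. DESeq2 gave 950, 183 and 1491 in wild type, 1152, 121 and 1885 in Sparc-null, 200 in bone marrow and 1 in liver for genotype, and 2 for each difference of genotype effects that involves liver. Scaling by the library total gave 1713, 61 and 1716 in wild type, 1068, 50 and 1771 in Sparc-null, and 0 for genotype in bone marrow. With only the compared groups, the counts were 38, 932 and 72 in wild type, 243 for liver against spleen in Sparc-null and 0 for genotype in bone marrow, and without wild type bone marrow replicate 1 as well, 233, 314 and 0 for the 3 comparisons that hold it. Voom gave 265, 1097 and 286 in wild type, 233 for liver against spleen in Sparc-null and 0 for genotype in bone marrow. At equal depth the counts were 255, 150 and 397 in wild type, 50 for liver against spleen in Sparc-null and 1 for genotype in bone marrow. The fits of the compared groups use their own spread, and in simulations with unequal spread they made fewer false calls but also recovered fewer changes where wild type bone marrow was compared. For the other alternatives the cause was not tested.

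The replicate number as a block gave 5, 1 and 419 in wild type, 223, 5 and 357 in Sparc-null and 1 for genotype in bone marrow. It ended the calls of 8 named identifiers, all but MGP_BALBcJ_G0020850 and those for liver against bone marrow (edgeR adjusted p = 0.0992 to 0.617). The numbers were not treated as pairing the libraries, since the labels do not say so and the correlations of same-numbered libraries' deviations ranged from -0.297 to 0.262, with no set of 3 or more pairs all over 0.1. In no pair did all correlate best with their own number.

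Leaving out 1 library at a time gave 172 to 1074, 3 to 224 and 401 to 1774 in wild type, 298 to 1178, 6 to 74 and 752 to 1782 in Sparc-null, 0 to 171 for genotype in bone marrow and 0 to 1 in liver. For bone marrow against spleen in wild type, the count was 257, 1074, 223 and 746 without bone marrow replicates 2 to 5, and 288, 174, 179, 172 and 199 without spleen replicates 3, 4, 7, 10 and 11. For liver against spleen in wild type it was 3 without liver replicates 3, 4 or 5 or spleen replicates 4, 7 or 11, 30 without liver replicate 2, 224 and 20 without wild type bone marrow replicates 1 and 3, and 10 and 25 without Sparc-null bone marrow replicates 3 and 4. For liver against bone marrow in wild type it was 1774 without bone marrow replicate 3, 416 without liver replicate 4 and 401 without liver replicate 5. In Sparc-null recipients, wild type bone marrow replicate 1 set the highest values (1178, 74 and 1782), and bone marrow replicate 4 the lowest for the bone marrow comparisons (298 and 752). Bone marrow against spleen was also moved by bone marrow replicate 3 (415) and spleen replicates 6 (392) and 7 (406). Liver against spleen in Sparc-null was moved by 18 of the 30 libraries, to 6 without liver replicate 6 or spleen replicates 3, 4 or 7, to 7 without spleen replicate 5, to 12 without liver replicate 5 or spleen replicate 6, to 17 without liver replicate 7, and to between 12 and 17 without any of 9 wild type liver and spleen libraries. The genotype count in bone marrow was 3, 22, 22 and 171 without wild type bone marrow replicates 1, 2, 4 and 5, 67, 60, 0, 1 and 35 without Sparc-null replicates 1 to 5, and 4 without wild type liver replicates 3 or 4, wild type spleen replicate 11 or Sparc-null spleen replicate 7.

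The share of higher calls moved with the scaling. For bone marrow against spleen it was 53.9% in wild type and 81.0% in Sparc-null with TMM, 95.3% and 91.1% with library totals, and 64.7% in Sparc-null with DESeq2. For liver against spleen it was 66.7% and 69.2% with TMM, 86.1% and 84.0% with the DESeq2 size factors and 80.3% and 32.0% with library totals. For liver against bone marrow it was 52.5% and 38.0% with TMM and 17.0% and 15.4% with library totals. It was 58.1% and 51.5% with the DESeq2 size factors and 60.7% and 56.6% with DESeq2. Library totals moved the median log2 fold change of all identifiers from -0.09 to 0.49, from 0.04 to 0.23 and from 0.16 to -0.24 in wild type, and for the bone marrow comparisons in Sparc-null from 0.02 to 0.27 and from 0.01 to -0.32.

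Pearson's r between genotypes was 0.696 for bone marrow against spleen and 0.597 for liver against spleen with identifiers of at least 10 CPM, and the cause was not tested. None of the 13 named identifiers changed direction under the alternatives run. The call of MGP_BALBcJ_G0035991 also ended at equal depth (edgeR adjusted p = 0.0576). The alternatives for the gene lists and the level of Sparc were not run for lack of gene names.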

Other observations

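The groups were also split at random, with 100 splits per comparison counted with the real one. In the 6 organ comparisons 1 of 100 splits, the real one, gave as many identifiers, which is the smallest share that these splits can give. Random splits treat the libraries as exchangeable, whereas bone marrow libraries had the larger spread. Where bone marrow was compared, the splits therefore do not exclude chance or unequal spread. The real counts and the highest of the other splits were 449 and 289 for bone marrow against spleen, 6 and 1 for liver against spleen and 786 and 583 for liver against bone marrow in wild type recipients, and 649 and 66, 26 and 12, and 1134 and 266 in Sparc-null recipients.

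Chance cannot be excluded for Sparc-null against wild type bone marrow, where 33 of 100 splits gave 7 identifiers or more and the highest gave 367. That count is far above the real one and may point to a structure of the samples, which was not tested. Unequal spread is a candidate source, since simulated data with the spread of each group gave 179 false calls in this comparison, but no test separated it from others. The genotype counts in spleen and liver and the 3 differences of genotype effects were 0 in edgeR, so any split gives as many (100 of 100) and the splits say nothing about chance there. The highest of the other splits was 0 for spleen and 1 for liver, and 63 for bone marrow against spleen, 1 for liver against spleen and 145 for liver against bone marrow for the differences of genotype effects.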
